A study of Mus musculus with 1600 samples.

How the data were processed

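Single cells of hind limbs of Scx-GFP transgenic C57BL/6 mouse embryos of 3 stages were captured on the Fluidigm C1 and made into libraries with Nextera XT, per the labels' protocols. Limbs were dissociated with collagenase and trypsin at each stage, per the labels' protocols. The deposited values were whole-number counts of reads per gene and cell, and the authors applied no normalization that the values show. Bowtie2, featureCounts and the mm10 build are named for these counts per the submitters' processing notes. Versions, the gene annotation and any use of unique molecular identifiers are not given in the sources used here, so counts were read as reads, which PCR can multiply. Another 1120 samples of the series were not analysed here.

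The table held 22738 entries for 22092 gene symbols and 480 cells. The 298 symbols listed more than once held 0.101% of all counts. Their entries with identical counts were kept once, and differing entries were added up. No entry lacked a symbol, and 0 mitochondrial entries were present, so the list of mitochondrial genes gave no result. No pair of cells held identical counts. Each cell was placed in its stage by its label and in its library pool by the pool index in its label. Each stage was 1 sample, so values are given without tests, and sums carry exact Poisson and shares exact Clopper-Pearson 95% intervals. Cells with under 1000 detected genes were left out, 1 at E10.5 and 2 at E12.5.

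Counts were summed over the kept cells of each stage and divided by the summed total to give CPM. Log2 ratios were computed with 5 added to each CPM for 13125 genes with a count in at least 10 kept cells. Folds are ratios of CPM without the addition. The method was tested on simulated data: of genes changed 4-fold or 8-fold all 100 of each were called in each comparison. Of unchanged genes 2 of 11667 were called at E12.5 against E10.5, 0 of 12616 at E15.5 against E12.5 and 1 of 12321 over the whole span. In the simulation the changed genes had at least 20 CPM, and all cells came from 1 mean profile with independent noise. It held no pool effects, cell classes or crosstalk, so these rates need not hold for genes carried by 1 pool or 1 cell. Genes named were the 12 with the largest ratio in each direction among called genes with a count in at least 20% of cells and 50 CPM in the higher stage, without ribosomal protein and predicted genes. Added to these were up to 4 members of each list and direction with at least 20 CPM, and a fixed set of tendon, cartilage, muscle, limb and globin genes. Within a class they were the 5 largest ratios in each direction among genes in at least 40% of cells. Isl1, Hoxc4, Hoxc5, Hoxc6, Hoxc11, Shh, Fgf8, Cma1, Cpa3, and list members named to complete a count lie outside this rule and were chosen after their values were seen.

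The 28 gene lists held 418 entries for 399 different symbols, of which 8 were found under an older symbol and 3 (Col6a3, Hbb-bt and Ahsp) were not matched. The lists cover cell types of the limb, Hox genes, limb identity and signalling, matrix, imprinted genes, globins, cell cycle, immediate-early and stress genes, glycolysis and ribosomal proteins. A list is described by its median log2 ratio, its called members, and its percentile among 10000 random lists matched on mean expression in 20 bins. The gene lists, the stage comparisons and all alternatives except the 3 named below as added were fixed before the data were examined. Of the 15 tests of explanations, 11 were written after the result was seen, and 4 after the files were first explored but before their own values were computed. Which of the lists the text leads with (fibrillar matrix, connective tissue, tendon, cartilage and limb bud) was chosen after seeing the data.

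Shares of cells with a gene were computed after each cell was thinned to 50000 counts, a total that at least 80% of cells of each stage reach. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 15 principal components, 15 neighbours and Leiden resolution 1 gave the clusters in scanpy 1.11.5. A cluster was named from the list with most markers among its top 100 genes, at least 3. This naming rule was set after seeing the data. An erythroid name also needed the list to hold 5% of the cluster's counts, a condition added after a cluster of 40 cells was first named by 3 globin genes that held 0.00911% of its counts. Scrublet called 0, 3 and 1 doublets at the 3 stages, which were left in. The test of sex was first read as decided and was changed to undecided, because the interval of its lowest share reaches below 5%. The test of crosstalk was split into globin and muscle genes after Cma1 and Cpa3 did not meet it. A cell lay above the crosstalk range of a gene with at least 3 counts and over 0.5% of the pool's counts of the gene. This limit was set after seeing the data from genes with 3000 or more counts in a pool. It is not an upper limit of crosstalk, since 1 of 390 values of other cells was 0.745%. Shares were therefore also taken with the limit at that value.

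Alternatives were the mean CPM of single cells, TMM factors from edgeR 4.0.16 in R 4.3.3, median-of-ratios size factors, 1 or 20 added to the CPM, all cells or those with 2000 genes, no gene filter, no doublets and leaving out each library pool. For shares they were no thinning, at least 3 counts, and for classes other resolutions and 1000 variable genes. Leaving out the highest cell of each gene in each pool, shares above the crosstalk range, and shares above the highest crosstalk seen, were added after seeing the data. Leaving out erythroid-like cells was not run, because no cluster kept that name. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Gene coordinates come from the GENCODE annotation of GRCm38, the assembly that mm10 holds.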

Results

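Gene expression was measured in single cells of hind limbs from C57BL/6 mouse embryos carrying a Scx-GFP transgene, at 3 embryonic stages named by the day of gestation, E10.5, E12.5 and E15.5. Scx encodes scleraxis, a transcription factor of tendon and ligament progenitors. The series addresses which cell types a mouse limb holds and how their transcriptomes differ between these stages. Cells were captured on the Fluidigm C1, a microfluidic chip that isolates single cells, and the labels name no sort for GFP. The set analysed here held 480 cells, with 120 labelled E10.5, 160 labelled E12.5 and 200 labelled E15.5. Cells sharing a pool index in their label formed 12 library pools of 40 cells, numbered 1 to 3 at E10.5, 4 to 7 at E12.5 and 8 to 12 at E15.5. Limbs of siblings were combined at each stage, so each stage was 1 sample without replicates and no test between stages was possible. Library pools are a technical split. A gene is called higher or lower when the log2 ratio of CPM (summed counts scaled by the stage total, with 5 added) reached 1 in size and every pool of a stage lay above every pool of the other.

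After 3 cells with under 1000 detected genes were left out, 477 cells remained, with 119 at E10.5, 158 at E12.5 and 200 at E15.5. The median cell held 272198 counts at E10.5, 250710 at E12.5 and 192228 at E15.5, over a range of 2681 to 1185267 counts. The median number of detected genes was 4763, 4653 and 4527. Summed over cells, the stages held 33742559, 46009284 and 46035725 counts. Intervals given below are exact 95% Poisson intervals for sums and exact Clopper-Pearson intervals for shares. They cover counting error only, since cells and reads are not independent samples of embryos. A gene with 0 counts in a stage was given a floor of 3 counts over that stage.

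Genes that mark hind limb and forelimb were read first, as a check of the labels. Pitx1, a hind limb transcription factor (GRCm38 chromosome 13, 55825051 to 55836192, minus strand), had 0 counts in the cells labelled E10.5. It reached 169 CPM (165 to 172) at E12.5 and 68.7 CPM (66.3 to 71.1) at E15.5. Tbx4, also a hind limb gene (chromosome 11, 85886422 to 85916097, plus strand), was at 5.63, 79.0 and 42.6 CPM. Isl1, which acts in hind limb initiation, and Hoxc10 (chromosome 15, 102966796 to 102971893, plus strand) also had 0 counts at E10.5. Hoxc10 was at 32.0 CPM at E12.5 and 25.7 CPM at E15.5. Tbx5, a forelimb transcription factor (chromosome 5, 119832668 to 119885219, plus strand), was at 67.9 CPM (65.1 to 70.7) in the cells labelled E10.5, 0.739 CPM at E12.5 and 6.32 CPM at E15.5. It was read in 73.1% of the cells labelled E10.5, against 6 of 158 cells at E12.5 and 10 of 200 at E15.5. By pool, Tbx5 was read in 76.9%, 75% and 67.5% of the cells labelled E10.5. Pitx1 was read in 79.1% of E12.5 cells and 55% of E15.5 cells, and in 0 of 119 cells labelled E10.5, which allows a share of up to 3.05%. The genes read in the cells labelled E10.5 thus went against the hind limb label, and directions drawn against that stage carry this difference.

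**Figure D1:**
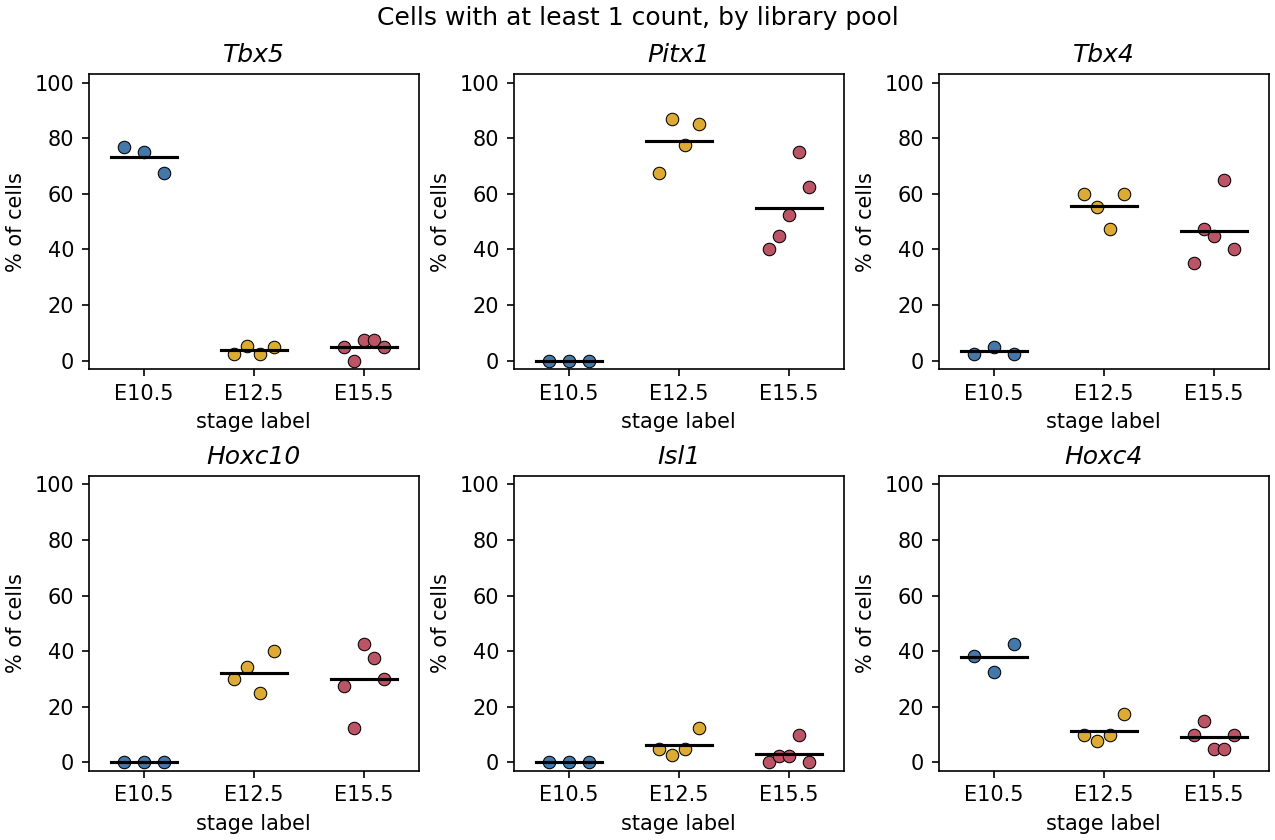
Share of cells (%) with at least 1 count of 6 limb genes in each library pool (points), by stage label on the horizontal axis, with the share over all cells of the stage as a line. Tbx5 lies between 67.5% and 76.9% in the pools labelled E10.5, while Pitx1, Hoxc10 and Isl1 are at 0 there.

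E12.5 against the cells labelled E10.5 asks how limb cells differ across the onset of tissue differentiation. Of the fixed lists, fibrillar matrix had 18 of 19 and connective tissue 8 of 11 genes higher at E12.5, while limb bud mesenchyme had 6 of 17 lower and 2 higher. Dcn and Lum, which encode small leucine-rich proteoglycans of collagen fibrils, were at 146 CPM (143 to 150) and 212 CPM (208 to 216) at E12.5. In the cells labelled E10.5 Dcn had 1 count and Lum was at 2.52 CPM (2.01 to 3.11), so Lum was 84.2-fold higher. Igdcc3, a cell surface protein of the immunoglobulin superfamily (chromosome 9, 65141189 to 65185872, plus strand), was 131-fold lower at E12.5, at 7.69 CPM (6.91 to 8.54) against 1006 CPM (995 to 1017). Sall4 (chromosome 2, 168748332 to 168767943, minus strand), a zinc finger factor of pluripotent and limb bud cells, was 104-fold lower at 1.28 CPM against 134 CPM. Of its 59 counts at E12.5, 56 came from 1 cell of pool 5, and without that pool the log2 ratio of Sall4, -4.46 over all pools, was -4.77. Of the genes with the largest ratios, Cxcl14 was 496-fold, Sulf1 583.7-fold, Tcfap2b 71.1-fold, Nfix 332-fold and Myl9 34.6-fold higher. Pitx1, Smoc2 and Hic1 had 0 counts in the cells labelled E10.5 and were at least 1897-fold, 822-fold and 723-fold higher. Egfl6 was at 83.3 CPM and Hoxd12 at 75.5 CPM at E12.5, with 1 and 3 counts in the cells labelled E10.5. On the lower side, Amica1 was 324-fold, Tbx5 91.9-fold, Zbtb16 62.0-fold, Prtg 29.7-fold, Fignl2 16.5-fold, Mogat2 16.4-fold, Pkdcc 11.6-fold, Hoxd9 10.4-fold, Lix1 9.14-fold and Asb4 8.47-fold lower. Several of these folds rested on 1 pool. Without pool 1, Lum and Cxcl14 had 1 count and Tcfap2b 0 counts in the cells labelled E10.5, and without pool 3, Sulf1 had 1 and Myl9 2 counts there. Without pool 7, Amica1 had 3 counts at E12.5 and Zbtb16 was 202-fold lower, without pool 6 Mogat2 was 103.7-fold lower, and without pool 4 Prtg was 52.5-fold lower. Pools 1 and 2 held 36.8% and 34.8% of the counts at E10.5, so that leaving out pool 1 or pool 2 made each bound against 0 counts at E10.5 lower by 1.58 or 1.53 times, and by up to as much the folds of Myl9 (either pool), Nfix (pool 1) and Lum, Cxcl14, Sulf1 and Tcfap2b (pool 2). The difference in limb identity genes applies to each of these directions, and Tbx5, Pitx1 and Hoxc10 are part of it.

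By group, 18 of 19 fibrillar matrix genes were higher at E12.5 than in the cells labelled E10.5, with a median log2 ratio of 2.01 (2.03 with genes at 0 counts set to their bound) at percentile 100 of random lists. Col1a1, the main chain of type I collagen, was 17.6-fold higher at 204 CPM, and Col6a2 was 39.0-fold higher. Among fibroblast and connective tissue markers 8 of 11 were higher, with a median of 2.21. Osr2 was 203-fold and Postn 96.9-fold higher, and Dcn, Lum, Postn and Col3a1 belong to both lists. Of 9 tendon markers 6 were higher, with a median of 1.49 (2.65 with bounds). Scx (chromosome 15, 76457452 to 76459458, plus strand) was 13.7-fold higher at 826 CPM (818 to 834) against 60.3 CPM (57.7 to 62.9), and its 4 pools at E12.5 ran from 507 to 1477 CPM. Kera, a keratan sulfate proteoglycan, was at least 660.3-fold higher, and Mkx, a tendon homeobox factor, was 34.2-fold higher. Of 17 cartilage markers 7 were higher, with a median of 1.39 (2.32 with bounds). Col2a1, the main collagen of cartilage (chromosome 15, 97975602 to 98004695, minus strand), was 8.42-fold higher at 416 CPM. Sox9, the transcription factor of cartilage progenitors (chromosome 11, 112782224 to 112787760, plus strand), was at 236 CPM (232 to 241) against 58.7 CPM (56.2 to 61.4), a log2 ratio of 1.92. Col9a2 was at least 594.3-fold higher. Of 9 joint markers 5 were higher, with a median of 1.15 (1.71 with bounds), among them Gdf5, a joint growth factor, which was at least 659.8-fold higher. Without pool 3, Col6a2 was 156-fold higher, and Osr2 had 0 counts in the cells labelled E10.5 and was at least 534-fold higher. Without pool 1, Mkx was 57.6-fold, Postn 61.2-fold, Osr2 128-fold and Col6a2 24.6-fold higher, without pool 2 Osr2 was 132-fold higher, and without pool 6 Col9a2 was at least 393-fold higher. The bounds of Kera, Col9a2 and Gdf5 were 1.58 times lower without pool 1 and 1.53 times lower without pool 2.

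Limb bud genes split. Of 17 markers of limb bud mesenchyme 2 were higher at E12.5 and 6 were lower than in the cells labelled E10.5, with a median log2 ratio of -0.29 at percentile 1.51 of random lists. The limb identity genes Tbx5 and Pitx1 differed between the 2 stages, as above. The 2 higher genes were Pitx1 and Tbx4. The lower genes were Sall4, Lin28a, Mycn, Lin28b, Meis2 and Meis1, with Lin28b, a regulator of let-7 microRNA maturation (chromosome 10, 45376620 to 45486395, minus strand), 5.83-fold lower and Lin28a at least 386-fold lower. Pool 5 held 909 of the 1332 Lin28b counts at E12.5, and without it the log2 ratio of Lin28b, -2.36 over all pools, was -3.34. Among 10 genes of the 5′ Hox clusters, which pattern the limb along its length, 4 were higher and 1 was lower. Hoxd13 was 9.43-fold and Hoxa10 2.60-fold higher, Hoxc10 at least 360.3-fold higher (228-fold without pool 1 and 235-fold without pool 2), and Hoxd9 was the lower gene. Of 18 limb signalling genes 3 were higher and 4 lower. Bmp2 was 12.54-fold, Wnt5a 3.53-fold and Hand2 2.14-fold higher, while Grem1, Etv4, Bmp7 and Dusp6 were 4.77-fold, 3.57-fold, 2.82-fold and 2.15-fold lower. The calls of Hand2, Bmp7 and Dusp6 were lost on leaving out 1 pool, with log2 ratios of 0.82 and 0.86 for Hand2 without pool 1 and pool 7, -0.76 for Bmp7 without pool 3, and -0.88 and -0.97 for Dusp6 without pool 2 and pool 6. Of 4 limb identity genes Pitx1, Tbx4 and Isl1 were higher and Tbx5 was lower. The call of Isl1 rested on few cells, since it was read in 10 of 158 E12.5 cells, at 15.1 CPM. In pool 4, 1 cell held 99.7% of its counts.

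Actc1 and the embryonic globins rested largely on single cells in this comparison. Differentiated muscle genes had a median log2 ratio of 3.53 (4.54 with bounds), yet 0 of 19 were higher. Chrna1, an acetylcholine receptor subunit of muscle, was lower, and without pool 7 the number of lower genes was 2. Actc1, cardiac alpha actin of early muscle, had a log2 ratio of 5.38, which was 1.25 without pool 7. Of 6 muscle progenitor genes, Vgll2 and Msc were higher and Pax3 was 58.3-fold lower, while Pax7 and Myod1 had log2 ratios of 1.20 and 1.27 without a call. Pax3 was read in 23 of 119 cells labelled E10.5, and its log2 ratio of -2.77 was -1.84 without pool 1. Without pool 7 Pax3 was 148-fold lower, and the log2 ratios of Pax7 and Myod1 were 0.82 and 0.53. Without the highest cell of each gene in each pool, 0 muscle progenitor genes were higher. The embryonic globins Hbb-y, Hbb-bh1 and Hba-x were at 310.2, 204 and 131 CPM in the cells labelled E10.5, and all of these counts came from pool 3, where 1 cell held 10191 of 10468 Hbb-y counts. None of the 7 red cell genes or of the 3 embryonic and 3 adult globins was called, with median log2 ratios of -1.95, -4.75 and -1.95. Without pool 3 the log2 ratio of Hbb-y, -5.98 over all pools, was 0, and those of Hbb-bh1 and Hba-a1, -4.43 and -1.95, were 0.96 and 0.41. Without pool 4 that of Hbb-bh1 was -5.39. Hba-a1 and Hba-a2 held identical counts in every stage, and their reads cannot be assigned to either copy. Myog was at a log2 ratio of 0.92, without a call.

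E15.5 against E12.5 asks how limb cells, summed over all cell types, differ between these stages. The sums also carry the mix of cells, with epithelial-like cells at 3 of 158 at E12.5 and 25 of 200 at E15.5. Higher skin genes were not told apart from a larger number of such cells. Of the fixed lists, tendon had 6 of 9, connective tissue 8 of 11 and skin epithelium 7 of 14 genes higher at E15.5, while limb bud mesenchyme had 8 of 17 lower. Tnmd, tenomodulin, a membrane glycoprotein of tendon (chromosome X, 133850980 to 133865577, plus strand), was 45.2-fold higher at 192 CPM (188 to 196) against 4.24 CPM (3.66 to 4.88). Thy1, a surface glycoprotein of mesenchymal and immune cells, was 805-fold higher at 105 CPM (102 to 108). Krt15 and Krt10, keratins of basal and suprabasal skin cells, were 25.4-fold and 19.4-fold higher. Anxa1 was 153-fold, Abi3bp 64.2-fold, Htra3 59.2-fold, Cd44 30.6-fold, S100a16 18.4-fold and Postn 14.3-fold higher. Dmkn and BC100530 had 0 counts at E12.5 and were at least 1179.7-fold and 786-fold higher. Among lower genes read in at least 20% of E12.5 cells and at 50 CPM or more there, Lhx2, Dach1, Dusp9, Mecom, Mab21l2, Nnat, Hoxd13, Uck2, Lhx9, Id1, Hmga2 and Nasp were between 3.63-fold and 5.599-fold lower. Lhx2, a homeobox factor of the distal limb bud, was at 15.4 CPM (14.3 to 16.6) against 86.4 CPM (83.7 to 89.1). Hmga2, a chromatin protein of undifferentiated cells, was at 303 CPM (298 to 308) against 1182 CPM (1172 to 1192). Without pool 4, Tnmd was 82.2-fold higher and Anxa1 had 3 counts at E12.5. Without pool 5 Krt15 was 213.9-fold higher, and without pool 6 S100a16 was 31.6-fold higher and Thy1 had 2 counts at E12.5. Without pool 7 Htra3 was 94.2-fold higher and Abi3bp had 2 counts at E12.5. Krt10 was 10.8-fold higher without pool 11, and Lhx2 was 9.58-fold lower without pool 9.

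Of 19 fibrillar matrix genes 16 were higher at E15.5 than at E12.5, with a median log2 ratio of 2.17. Col1a1 was 11.2-fold higher at 2287 CPM (2274 to 2301), and Eln, which encodes elastin, was 11.2-fold higher. Of 11 connective tissue markers 8 were higher, with a median of 2.24 (2.36 with bounds), among them Dpt at 205-fold and Ogn at 9.51-fold. Of 9 tendon markers 6 were higher, with a median of 2.20. These were Tnmd, Thbs4, Fmod, Tnc, Col14a1 and Col12a1, with Thbs4 at least 670.3-fold (330.4-fold without pool 11) and Fmod 10.1-fold higher. Without pool 6, Dpt had 1 count at E12.5. Scx itself was at 226 CPM (221 to 230) against 826 CPM (818 to 834), a log2 ratio of -1.85 without a call. Its pools at E15.5 ran from 61.7 to 780.3 CPM, the highest being pool 11, and without pool 11 the log2 ratio was -2.83 and Scx was called lower. Without pool 4, the highest at E12.5, it was -1.40. Of 17 cartilage markers 1 was higher, Lect1 (chondromodulin) at 7.08-fold (11.5-fold without pool 6), while the list's median was 1.05. Without pool 6 the number higher was 4, without pool 12 it was 2, without doublets it was 2, and without the highest cell of each gene in each pool it was 0. Acan, the cartilage proteoglycan aggrecan, was at 49.0 CPM (47.0 to 51.0) against 2.80 CPM (2.34 to 3.33), and Col2a1 at 723 CPM against 416 CPM, both without a call. Pool 6 held 127 of the 129 Acan counts at E12.5 and pool 9 held 1138 of the 2255 at E15.5. The log2 ratio of Acan, 2.79 over all pools, was 3.42 without pool 6 and 3.07 without pool 12, with Acan called higher in either case, and 2.14 without pool 9. Sox9 was at 143 CPM (139 to 146) with a log2 ratio of -0.71, also without a call.

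Of 17 limb bud markers 8 were lower at E15.5 than at E12.5 and 0 were higher, with a median log2 ratio of -0.82. Lin28b was 46.0-fold, Lhx9 4.28-fold and Pitx1 2.46-fold lower. The log2 ratio of Lin28b, -2.59 over all pools, was -1.61 without pool 5, and Lin28b was 19.3-fold lower without pool 5 and 109.8-fold lower without pool 9. Of 10 Hox genes Hoxd13 and Hoxd12 were lower, at 4.56-fold and 4.00-fold. Of 18 limb signalling genes Hand2 and Cyp26b1, which degrades retinoic acid, were lower. The number was 4 without pool 4 or pool 10 and 1 without pool 5, 6 or 11. Of 14 skin epithelial markers 7 were higher, with a median of 2.42 (2.76 with bounds), among them Krt14, a basal keratin, at 388 CPM (383 to 394) against 63.7 CPM (61.5 to 66.1). Pool 5 held 1541 of the 2933 Krt14 counts at E12.5, and Krt14 was 6.09-fold higher over all pools and 9.72-fold higher without pool 5. Endothelial, mural, myeloid and Schwann cell or neural crest lists had median log2 ratios of 0.56, 0.57, 1.89 and 1.15 with 0 genes called. The myeloid number was 2 without pool 5 or pool 9. Without pool 6 the endothelial number was 1, as was the mural number without pool 6, 7 or 8 and the Schwann cell number without pool 6 or 8. Differentiated muscle genes had a median of -1.03 with 0 called, or 1 without pool 10. Of the muscle regulators, Myod1, Myog, Pax3 and Pax7 had log2 ratios of 0.47, 0.79, 1.09 and -0.47 without a call, and that of Pax3 was 0.03 without pool 12. Without pool 7 those of Myod1 and Pax7 were 1.20 and -0.09, and that of Myog was 1.09 without pool 5 and 0.24 without pool 9.

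**Figure D2:**
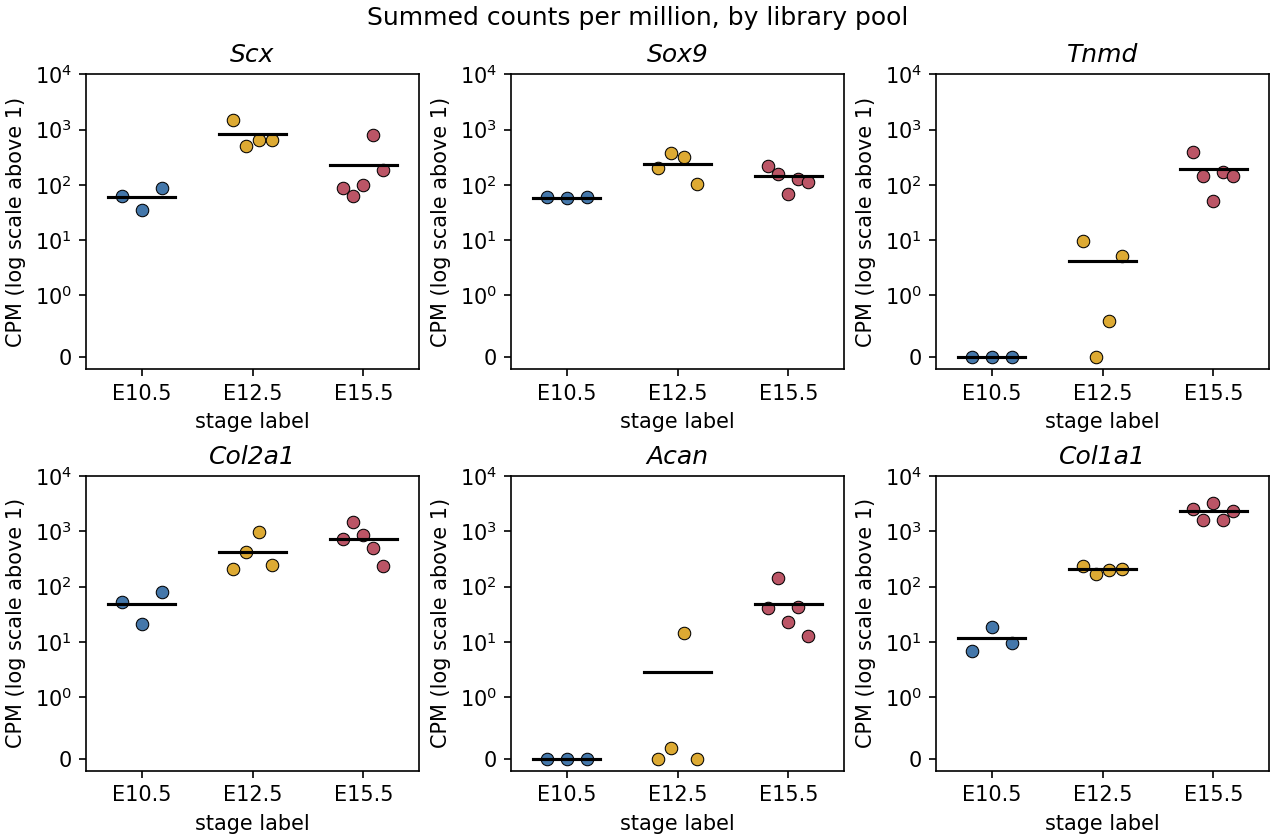
Summed CPM of 6 tendon, cartilage and matrix genes in each library pool (points), by stage label, with the value over all pools of the stage as a line; the vertical axis is logarithmic above 1 and linear below. Col1a1 pools do not overlap between stages, while the Scx pools at E15.5 run from 61.7 to 780.3 CPM.

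Over the whole span, E15.5 against the cells labelled E10.5, the genes with the largest ratios on the higher side included matrix genes such as Col1a1 and Lum beside the keratin Krt14 and the transcription factor Nfix. Col1a1 was 197-fold, Lum 240.1-fold, Col6a2 233-fold, Ogn 229.6-fold, Pmp22 178-fold and Col6a1 106-fold higher. Postn was 1387-fold, Nfix 794-fold and Cxcl14 670.1-fold higher, and Krt14 at least 4367-fold. Dcn was at 844 CPM (835 to 852) and Egfl6 at 222 CPM, each with 1 count in the cells labelled E10.5. Without pool 1, Lum and Cxcl14 had 1 count there and Pmp22 was 1458-fold higher. Without pool 2 Col6a1 was 311-fold and without pool 3 Col6a2 934-fold higher. Without pool 1 the folds of Col6a1, Col6a2, Postn and Nfix and the bound of Krt14 were 1.58 times lower. Without pool 2 that bound and the fold of Cxcl14 were 1.53 times lower, with Lum at 158-fold and Pmp22 at 118-fold. All 11 connective tissue markers and 18 of 19 fibrillar matrix genes were higher, with median log2 ratios of 3.35 (5.71 with bounds) and 4.49 (4.70 with bounds). Of 9 tendon markers 7 were higher, and the exceptions were Thbs4, called higher without pool 3, and Scx. Scx had a log2 ratio of 1.82, which was 0.84 without pool 11 and 2.03, a call, without pool 9. Sox9 was higher with a log2 ratio of 1.21, a call lost without pool 8, where it was 0.94. Of 17 cartilage markers 7 and of 14 epithelial markers 10 were higher. Of 7 bone and hypertrophic cartilage genes Dlx5 and Runx2, a transcription factor of bone formation, were higher, 4 without pool 12. Lower were Igdcc3 at 1544-fold, Amica1 at 648-fold, Lin28b at 268-fold, Mogat2 at 131-fold, Prtg at 76.9-fold, Hsd11b2 at 59.4-fold, Trim71 at 40.9-fold and Hoxd9 at 30.2-fold. Asb4, Dusp9 and Lix1 were 18.1-fold, 14.1-fold and 12.1-fold lower, and Sall4 had 3 counts at E15.5. All 30 Igdcc3 counts at E15.5 came from pool 12, and without it the log2 ratio of Igdcc3, -7.48 over all pools, was -7.66. Without pool 9 Lin28b was 641-fold and Prtg 137-fold lower, without pool 8 Mogat2 was 241.5-fold lower, without pool 11 Hsd11b2 was 256-fold lower, and without pool 12 Trim71 was 75.1-fold lower. Of 17 limb bud markers 10 were lower and 2, Pitx1 and Tbx4, higher. The difference in limb identity genes of the cells labelled E10.5 applies to each of these directions.

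Calls rested on size and on separation of pools. At E12.5 against the cells labelled E10.5, 19.8% of 13125 genes had pools that did not overlap, where random order of pools gives 5.71%. At E15.5 against E12.5 the share was 9.05% against 1.59%, and over the whole span it was 24.8% against 3.57%. The median log2 ratio of all genes was 0.17, -0.04 and 0.15 in these comparisons. Scaling by edgeR's TMM factors moved the first of these by -0.13, and median-of-ratios size factors moved it by -0.15 and the whole-span value by -0.11. Of the calls at E12.5 against the cells labelled E10.5, 73.3% were higher, and TMM and size factors gave 58.1% and 55.1%.

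Scx and Sox9 mark progenitors of tendon and cartilage, and the share of cells with both was compared after each cell was thinned to 50000 counts. This left 115, 149 and 185 cells and left out 4, 9 and 15 shallower cells. Scx was read in 26.1% (18.3 to 35.1) of thinned cells labelled E10.5, 77.9% (70.3 to 84.2) at E12.5 and 41.1% (33.9 to 48.5) at E15.5. Without thinning the shares were 40.3%, 94.9% and 56.5%. Sox9 was read in 41.7%, 66.4% and 44.3% of thinned cells and in 56.3%, 79.7% and 56% of unthinned cells. Both genes were read together in 12.2% (6.82 to 19.6), 50.3% (42.0 to 58.6) and 18.9% (13.5 to 25.3) of thinned cells. The products of the single shares were 10.9%, 51.7% and 18.2%, each within the interval of the joint share. Background was read in endothelial-, epithelial- and myeloid-like cells, which should lack Scx. At E15.5, 39.0% of 41 thinned cells of these classes held Scx and 29.3% held Sox9, at a median of 240778 counts against 192228 for the stage. By this measure, any count after thinning, the Scx share at E15.5 did not stand apart from background. Above the crosstalk range of the pool, without thinning, Scx was in 23.5% (17.8 to 30.0) of E15.5 cells against 6.82% (1.43 to 18.7) of 44 background cells. Sox9 was then in 34% of E15.5 cells against 22.7% (11.5 to 37.8) of these background cells, and both genes were in 8.5% against 0 of 44. Sox9 thus did not stand apart from these classes, but they were chosen as cells that should lack Scx. Whether they lack Sox9 was not tested, so this does not show that Sox9 reads at E15.5 are background. Above the range, Scx, Sox9 and both were in 1, 3 and 1 of 7 background cells at E12.5 and in 1, 2 and 0 of 5 at E10.5, too few to compare. After thinning, at E12.5, 3 of 6 such cells held each gene, at a median of 461991 counts against 250710, and at E10.5 1 of 5, at 373073 against 272198.

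Other genes fixed for this comparison were read in the same way. Tnmd was read in 0, 4.03% and 27.6% of thinned cells, and in 0, 5.06% and 49.5% without thinning, against 17.1% of thinned background cells at E15.5. Above the crosstalk range Tnmd was in 14.5% (9.93 to 20.2) of E15.5 cells against 0 of 44 background cells. Col2a1 was read in 20.9%, 69.1% and 73.0% of thinned cells and 31.9%, 86.1% and 91.5% without thinning, with a background of 56.1% at E15.5. With at least 3 counts after thinning its shares were 11.3%, 55.0% and 44.9%. Above the crosstalk range they were 16.0%, 46.8% and 28.5%, so the direction from E12.5 to E15.5 depended on the measure. Pax3, a muscle progenitor factor, was read in 10.4%, 2.01% and 3.24% of thinned cells and 19.3%, 6.96% and 5.5% without thinning. Pax7, Myod1 and Myog were read in 0 thinned cells labelled E10.5. At E12.5 they were in 2.01%, 4.70% and 2.68% of thinned cells and at E15.5 in 3.78%, 7.57% and 4.32%. Without thinning they were in 6, 10 and 5 of 158 cells at E12.5 and in 7, 21 and 11 of 200 cells at E15.5. Without pool 7 the thinned share of Myod1 at E12.5 was 0.909%. Pitx1 was in 0, 65.8% and 43.8% of thinned cells, with a background of 12.2% at E15.5. Tbx4 was in 2.61%, 47.7% and 33.5%, and Tbx5 in 51.3%, 2.01% and 3.78%.

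Reads of a gene with many counts in 1 cell appeared across that cell's library pool. In 10 pairs of a gene and a pool with 3000 or more counts of the gene, 1 cell held at least 95% of these counts, and the pairs came from 1 cell each of pools 3, 7 and 10. The gene was then read in 74.4% to 100% of the other cells of the pool, with a median of 91.0%. It was read in a median of 2.54% of cells in the other pools of the stage. The median other cell held 0.0458% of the pool's counts of the gene, and the highest 0.745%. With fewer counts the spread was smaller, as for Myh3 in pool 9, with 800 counts and 99.4% of them in 1 cell, read in 6 of 40 cells. Hbb-y was read in all 40 cells of pool 3 and in 0 cells of pools 1 and 2. Outside the epithelial-like class, Krt14 was read in 78.3% of E15.5 cells, at a median of 181344 counts per cell. Krt14 was read above the crosstalk range, set at 3 counts and 0.5% of the pool's counts of the gene, in 5.71% of them. This range does not cover all crosstalk seen, as 1 of 390 values of other cells in these pairs, for Hbb-y, lay past it. By the same measure Scx was read in 22.7%, 44.3% and 23.5% of cells, Sox9 in 37.8%, 50% and 34%, and both in 10.9%, 22.8% and 8.5%. The limit is a share of each pool's own counts of the gene, which for Scx were 420 in pool 2 and 17299 in pool 4. It therefore asks for more counts in some pools than in others, and these shares are not on the same scale across stages. Tbx5 was read above this range in 48.7%, 52.5% and 45% of the cells of the pools labelled E10.5.

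**Figure D3:**
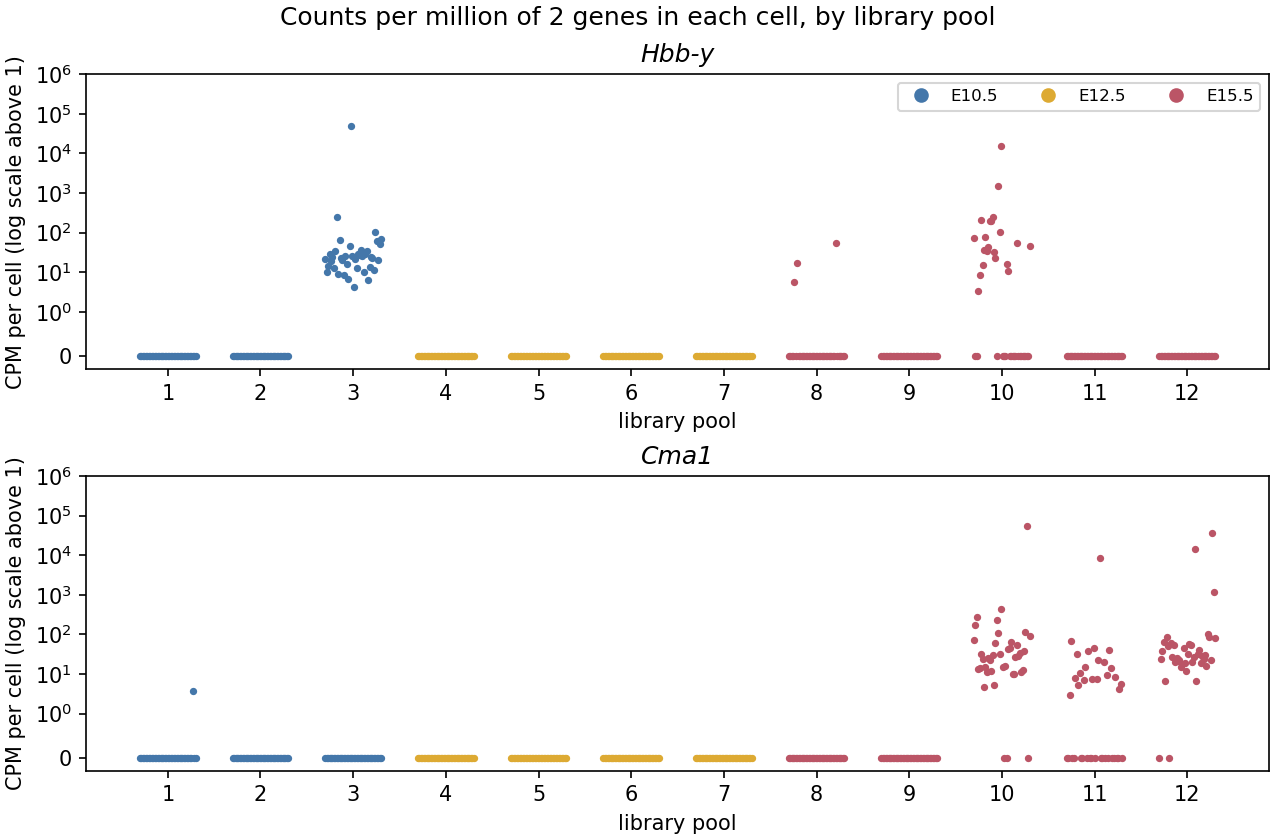
CPM of Hbb-y and Cma1 in each cell (points) by library pool on the horizontal axis, colored by stage label; the vertical axis is logarithmic above 1. Hbb-y is read in all 40 cells of pool 3 and in none of pools 1 and 2.

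Clustering of all cells gave 10 clusters, named from the fixed markers. Cells of the mesenchyme grouped by stage, so that only the endothelial-, epithelial-, myogenic- and myeloid-like classes were compared in size. Endothelial-like cells made up 4.20% (5 of 119), 1.90% (3 of 158) and 5.5% (11 of 200) of cells, with overlapping intervals. Epithelial-like cells numbered 0 of 119, which allows a share of up to 3.05%, then 3 of 158 and 25 of 200. Their share was 1.90% (0.393 to 5.45) at E12.5, and its interval was 8.26% to 17.9% at E15.5. Myogenic-like cells numbered 0, 7 and 13, with shares of 4.43% (1.80 to 8.92) at E12.5 and 6.5% (3.51 to 10.9) at E15.5. These numbers count cells of named clusters, so a 0 does not show that a cell type was absent. Pax3 was read above the crosstalk range in 8 of 119 cells labelled E10.5 (6.72%). Myeloid-like cells numbered 0, 1 and 8, a share of 4% (1.74 to 7.73) at E15.5. Among the 10 highest genes of the myeloid-like cluster were the mast cell genes Cma1, Cpa3, Hdc and Tpsb2 beside Fcer1g, Tyrobp and Pf4 of the fixed list, so this class does not tell myeloid from mast cells and its size is not that of either type alone. At a clustering resolution of 0.5 no myeloid-like class was named, and the 1 cell at E12.5 came from pool 5. A cluster of 40 cells, 20% of E15.5 cells, stayed unnamed.

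**Figure D4:**
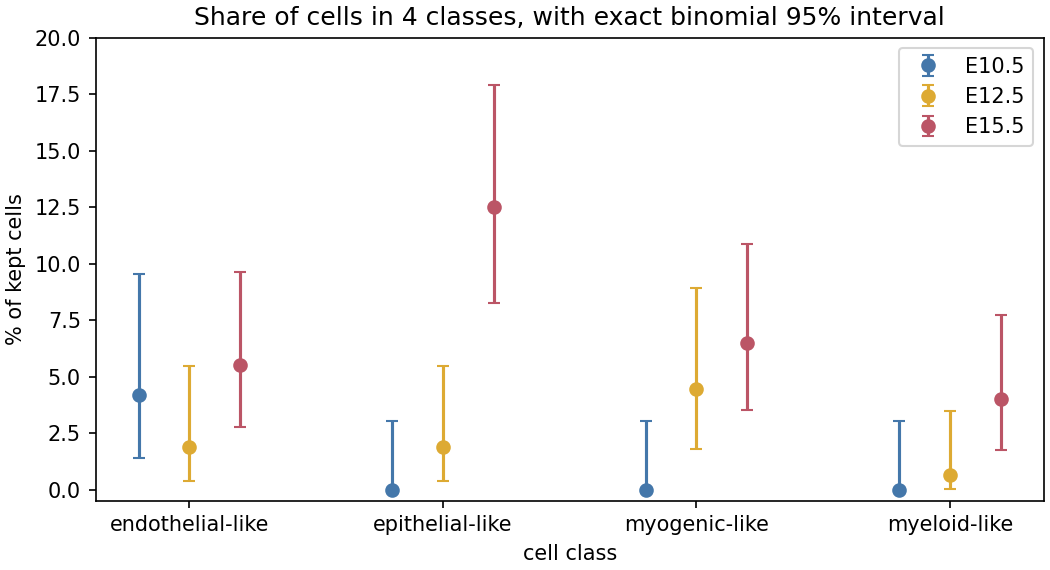
Share of kept cells (%) in 4 named classes by stage label (points), with exact binomial 95% intervals as bars. The epithelial-like class holds 3 of 158 cells at E12.5 and 25 of 200 at E15.5, with intervals that do not overlap.

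Within the chondrogenic-like class, 54 cells of E15.5 were set against 50 of E12.5. Cluster 5 held all 54 cells of E15.5, while clusters 2 and 5 held 38 and 12 of the E12.5 cells. Fmod and Tnmd, both of tendon, were 29.4-fold and 22.1-fold higher at E15.5, and Postn was 14.7-fold higher at 655 CPM against 44.6 CPM. Htra3 and Anxa1 had 0 counts at E12.5 and were at least 317-fold and 282-fold higher. Ckap2l, Ift140, B3gnt1, Kdm6a and Ube2c were 26.9-fold, 18.4-fold, 16.4-fold, 16.4-fold and 12.4-fold lower. Without pool 8 Tnmd was 12.2-fold and Fmod 19.0-fold higher and Ckap2l 17.5-fold lower. Without pool 4 Tnmd was 36.2-fold higher, and Ckap2l and B3gnt1 were 16.9-fold and 10.1-fold lower. Postn was 30.1-fold higher without pool 5 and Fmod 72.5-fold without pool 6. Ckap2l was 111-fold lower without pool 10, and Ift140 and B3gnt1 were 51.0-fold and 43.9-fold lower without pool 11. By size alone, a log2 ratio of at least 1 with 5 added to each CPM, 10 of 17 cartilage and 14 of 19 fibrillar matrix genes were higher. Markers of other cell types also reached this size. They were 6 of 9 tendon, 7 of 11 connective tissue and 5 of 14 epithelial genes, with 0, 0 and 1 lower. These are sums over the class and do not show that single cells held markers of several types. Cluster 5, which held all 54 cells of E15.5, was named from 8 cartilage markers among its top genes, with 4 tendon markers second. Most E12.5 cells of the class came from cluster 2, so the cartilage and tendon numbers partly restate how clusters were formed and named. The 5 higher epithelial genes were at 9.4 to 31.7 CPM at E15.5, and crosstalk was not taken out of these sums. Of 20 genes of the G2 and M phases 14 were lower by the same size of log2 ratio, with a median of -1.48. In the limb-bud-like class cluster 0 held the cells labelled E10.5 and cluster 3 nearly all cells of E12.5. Cluster 3 was named from 3 markers, Msx1, Prrx2 and Lhx9, the fewest allowed. Igdcc3, Prtg and Sall4 were among the 10 highest genes of cluster 0. The contrast within this class is thus nearly that of the clusters and of the stages. Here too other groups reached the same size of log2 ratio at E12.5. They were 7 of 11 connective tissue, 6 of 14 epithelial and 9 of 16 immediate-early and stress genes, with 0 lower in each. There Adamts5 was 487-fold, Sulf1 502-fold and Cxcl14 291-fold higher at E12.5, and Igdcc3 was 711-fold, Tbx5 102-fold and Prtg 38.1-fold lower. Pitx1 was at least 1353-fold higher and Sall4 at least 1408-fold lower, while Dcn had 1 count in the cells labelled E10.5 and Amica1 3 counts at E12.5. Without pool 1 Cxcl14 had 1 count and without pool 3 Sulf1 had 1 and Adamts5 0 counts in the cells labelled E10.5. Without pool 4 Prtg was 125.6-fold lower, without pool 5 Sulf1 was 319.5-fold higher, and without pool 6 Igdcc3 was 2049-fold lower. Without pool 1 Pitx1 was at least 852-fold and Adamts5 306-fold higher. Without pool 2 Pitx1 was at least 875-fold, Adamts5 315-fold, Sulf1 325-fold and Cxcl14 188-fold higher. These values within a class carry no condition on library pools.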

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

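Removal of the highest cell of each gene in each pool, shares above the crosstalk range, and shares above the highest crosstalk seen, were chosen only after the results were seen; the other alternatives were planned. No paired analysis was possible because each stage was 1 sample and library pools share no number across stages. Among the values recomputed, 6982 log2 ratios of genes stayed within their limits and 268 moved, as did 1361 and 97 numbers of called list members, 1183 and 275 list medians, 299 and 61 gene shares and 166 and 23 class shares. For a gene the limit was the standard deviation of its log2 CPM between pools, both stages combined. Leaving out a pool gave 3211 of the values that stayed and 9 that moved, judged by the spread between those same pools. Dropping the gene filter could not move any of its 403 values. The numbers for genes thus do not measure how stable the folds are. Among the genes recomputed, no called gene changed its sign under any alternative run. Leaving out a pool could not change it, because a call requires pools that do not overlap. Changing the value added to the CPM or dropping the gene filter could not change it either. Genes without a call did change sign, as Hba-a1, at -1.95 at E12.5 against E10.5 and 0.41 without pool 3. The lower depth at E15.5 limits shares of cells more than sums, and genes at the floor in both stages give no ratio. The alternative without erythroid-like cells was not run, because no cluster kept that name.

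The number of cartilage markers higher at E15.5 than at E12.5, 1 over all pools, was 2 without doublets and 0 without the highest cell of each gene in each pool, and ran from 1 to 4 when a library pool was left out. Without thinning, Scx was read in 40.3%, 94.9% and 56.5% of cells by stage, Sox9 in 56.3%, 79.7% and 56%, and both in 22.7%, 75.9% and 30.5%. With at least 3 counts after thinning, Scx was in 59.1% of E12.5 and 24.3% of E15.5 cells, Sox9 in 26.1%, 50.3% and 34.1%, and both in 31.5% of E12.5 and 7.57% of E15.5 cells. Above the crosstalk range, Scx was in 44.3% and 23.5%, Sox9 in 50% and 34%, and both in 22.8% and 8.5% of E12.5 and E15.5 cells. Above the highest crosstalk seen these were 38.6% and 20%, 44.9% and 32%, and 17.1% and 6.5%. These stricter rules lower each share by construction, and the share at E12.5 stayed above those at the other stages for both genes. The crosstalk limits are shares of each pool's own counts of the gene, so they differ between pools and stages. The myeloid-like share, 0.633% at E12.5 and 4% at E15.5, was 0 at both stages at resolution 0.5, and the cause was not tested. Leaving out a pool gave 0% to 0.847% for this class at E12.5 and 3.13% to 5% at E15.5.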

Other observations

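Some genes of other groups were also called higher or lower between stages. Of 11 imprinted growth genes Dlk1, Plagl1, H19 and Meg3 were higher at E15.5 than at E12.5, by 5.32-fold, 4.85-fold, 2.71-fold and 2.37-fold. Against the cells labelled E10.5, Cdkn1c, a cell cycle inhibitor, was 4.47-fold higher at E12.5 and Mest 2.37-fold lower. Of 20 genes of the G1 and S phases 10 were lower at E15.5 than in the cells labelled E10.5, among them Mcm7 and Cdc6 at 3.86-fold and Uhrf1 at 3.46-fold, with a median log2 ratio of -0.99. Of 20 genes of the G2 and M phases 3 were lower and Nusap1 was higher over the same span, with a log2 ratio of 1.08 that was 1.74 without pool 2, and 0.71 and 0.97, no longer a call, without pool 1 and pool 3. The number lower was 1 without pool 9 and 5 without pool 12, and also 5 with TMM or size factors. Pkm2, Pfkl and Eno1 of the 12 glycolysis and hypoxia genes were lower at E15.5 than in the cells labelled E10.5. The log2 ratio of Eno1, -1.05, was -0.93 without pool 2, -0.996 without pool 11 and -0.97 without pool 12, each ending its call. Ribosomal protein genes had a median log2 ratio of 0.30 at E15.5 against E12.5, and 0 of 77 were called. Of 5 neuronal genes Tubb3 was lower at E15.5 than at E12.5, and not so with 20 added to the CPM. Its counts at E15.5 all came from pool 11. Shh and Fgf8, signals of the limb bud margins, were at 2.46 and 4.77 CPM in the cells labelled E10.5, while Shh had 0 counts at the later stages. Pool 2 held 81 of the 83 Shh counts and pool 1 held 157 of the 161 Fgf8 counts, so without that pool nearly all of either value is gone.

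Tests of the limb identity genes other than the Hoxc4 and Hoxc11 test, tests of crosstalk and free RNA, the test of sex at E15.5 alone, and the digestion value were chosen only after the result was seen, while the other 4 tests were written after the files were first explored but before their own values were computed. The cells labelled E10.5 held Tbx5 and no Pitx1, Isl1 or Hoxc10. Too little depth is argued against, since 2846 Pitx1 counts were expected at 50% of the E12.5 rate and 0 were observed, and so is crosstalk, since at least 45.0% of the cells in each pool held Tbx5 above its range, and at least 40% above the highest crosstalk seen. Of 5 endothelial-like cells labelled E10.5, 2 also held Tbx5 above either limit, too few to compare. That forelimb bud cells entered this stage may explain the pattern, since the lowest share of cells with Tbx5 in a pool was 67.5%, and a biological difference of stage was not tested. Hoxc4, a more anterior Hox gene, was 3.68-fold higher in the cells labelled E10.5 than at E12.5 (5.82-fold without pool 7), but Hoxc11 was at the floor at both stages, so this second gene set leaves the matter open. Hoxc5 and Hoxc6, looked at after the fact, were at 7.26 and 11.9 CPM in the cells labelled E10.5 and at 1.46 and 1.96 CPM at E12.5, which goes the same way. Without pool 6 Hoxc5 was at 0.214 CPM at E12.5, without pool 7 Hoxc6 was at 1.299 CPM there, and Hoxc5 was at 5.604 CPM at E15.5 and at 1.15 CPM without pool 8.

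Genes with 3000 or more counts in a pool, at least 95% of them in 1 cell, were read in most other cells of that pool. Over all 10 pairs, which came from 3 cells, 8 were in most cells of their own pool and in under 10% of cells of other pools, and the median share in other pools was 2.54%. For the mast cell genes Cma1 and Cpa3, at least 51.3% of the other cells held the gene in E15.5 pools with a cell at 1000 CPM or more (pools 10, 11 and 12), against at most 5.00% (0.611 to 16.9) of cells in pools 8 and 9, which had no such cell. For globin and muscle genes, at most 5.93% of cells in other pools held the gene, against at least 74.4% in its own pool. Both parts argue against free RNA of a suspension shared by the stage as the cause and are consistent with reads assigned to the wrong cell within a pool, a hypothesis found and tested on the same data.

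Immediate-early and stress genes were higher at later stages. Of 16 genes 8 were higher at E12.5 and 13 at E15.5 than in the cells labelled E10.5, and 9 were higher at E15.5 than at E12.5. Fos was at 156 CPM in the cells labelled E10.5 and 1390.0 CPM at E15.5, and its median per cell at 29.3, 429 and 1136 CPM. Set against all cells labelled E10.5, the lowest median log2 ratio over the E15.5 clusters was 1.34. Of the cells labelled E10.5, 114 of 119 were limb-bud-like, and most E15.5 clusters were of classes without cells there. Cell class was thus not held constant, and a different mix of cell classes was left open as a cause. After thinning the median was 2.61. Thinning keeps each gene's expected share of a cell's counts. It therefore shows only that the weight of deep cells did not carry the ratio, and does not otherwise test counts per cell. Longer digestion of older limbs may contribute and cannot be told apart from stage, at a median log2 ratio of 2.45, because each stage was dissociated on its own.

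That any stage held cells of 1 sex only was tested as a hypothesis. The lowest share of cells with at least 2 Y-linked genes was 5.04% (1.87 to 10.7) at E10.5, beside 56.3% with Xist and no Y-linked gene, and at E12.5 the share was 6.33% (3.08 to 11.3), which leaves both stages open. At E15.5, 21 of 200 cells held at least 2 Y-linked genes, with a lower limit of 6.62%, beside 48.5% with Xist and no Y-linked gene, which argues against cells of 1 sex there. Of those 21 cells 11 also held Xist, and above the highest crosstalk seen the number was 20, with a lower limit of 6.22%.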
